A study of Drosophila melanogaster with 4 samples.

How the data were processed

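H3K4me1 ChIP and input DNA were prepared from formaldehyde-treated, sonicated chromatin of head nuclei of wild-type Oregon-R flies, with 2 ChIP replicates and 2 input replicates, per the labels' protocols. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited region lists called for each ChIP replicate alone, with the input of the same number as its control per the labels, and 1 list for the replicate set. The peak caller, its threshold and its filters were not given in the sources used here. Coordinates are 1-based and on FlyBase release 5, per the file headers. Each region carried a score deposited by the authors, an enrichment value whose scale the headers do not state. In the report it served to describe, rank or filter regions within 1 list and for a rank correlation between the replicates; the closing tests also compared replicate 2 scores at matched replicate 1 score and took the scores apart into ratios. No table of read numbers was at hand, so the depth of each library was unknown, and intervals on shares of regions cover counting error over regions only. No file of the input libraries was used here; the input numbers of the closing tests are estimates from the scores of the ChIP lists.

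Groups and replicate numbers came from the labels. With 2 replicates of 1 condition, values are given per replicate, with mean and SD where they are averaged, and no test between conditions was possible. Chromosome lengths were read from the file headers; the unplaced extra scaffolds were left out of shares of the sequence because no list had a region there. Regions counted as shared when they overlapped by at least 1 bp. The share of shared regions was set against 10000 circular shifts of the other replicate within each chromosome, one-sided, and the median gap between neighbouring regions against 1000 random placements without overlap, one-sided. Differences of medians and Spearman correlations were tested by two-sided permutation with 100000 resamples. Shares have exact Clopper-Pearson 95% intervals. The covered share was also computed in windows of 1 Mb, where the log2 ratio of replicate 2 over replicate 1 (0.5 percentage points added to both) was compared between X and autosome windows by permutation of the windows, and ratios of covered shares have intervals from 2000 bootstrap draws of windows. The autosome arms are 2L, 2R, 3L and 3R, and the proximal part of an arm is the 2 Mb at the centromeric end of its sequence. The heterochromatic (Het) sequences are listed apart from the arms in the file headers.

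The main tests, 36 of the 61 computed alternatives and the rule for named regions were fixed before the data were examined. The comparison of X and autosome windows, the proximal parts, the score quartiles, the joined domains, the tests on whole-number ratios and 25 alternatives were added afterwards; these alternatives concern the X in replicate 2, spacing, the score and width of shared regions, the named regions and the shared regions without the X. The rule named the 10 highest-scoring and the 5 widest combined-list regions that overlap a region of both replicates, and per replicate the 3 highest-scoring regions missing from the other. The widest joined domains, the extreme windows and the longest gaps were chosen after their values were seen. Alternatives covered the higher-scoring 50% of each list, regions joined across gaps of up to 500 bp, overlap of at least 50% of a region or 50% reciprocal, equal numbers of top-scoring regions, the 5 large arms only, independent random placement, circular shifts for the differences of medians, each replicate alone, width in place of score, and regions per Mb in place of covered share. Alternatives used 1000 shifts or placements and 10000 resamples. Tests of promoters and of gene lists had been planned but were left out, because the gene table at hand is of genome release 6 and coordinates were not converted; no gene is named for the same reason.

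For the closing tests, each score was taken as a common factor times a ratio of whole numbers on a log2 scale, and the ratio in lowest terms was found by continued fractions within a relative tolerance of 2e-14. The factor was set so that small primes divided the numerators and the denominators about equally often. The numbers per kb were read at the 69.6% quantile of the reduced numbers, which is the median of those that needed no reduction if 60.8% of pairs of whole numbers share no factor. These numbers are estimates and served only the closing tests, on the X in replicate 2 and on the highest scores, and to describe the replicate set and the highest replicate-only scores. The functions were run on simulated data made from the real lists. Among 40 pairs of the 7785 replicate 1 regions and a circularly shifted replicate 2 list, 5% had p at or below 0.05. A rate near 5% was built in there, because the test itself uses such shifts. All ratios simulated on the widths of the 3 lists were recovered. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.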

Results

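Histone H3 monomethylated at lysine 4 (H3K4me1), a mark of enhancers and of the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing in head nuclei of wild-type Oregon-R *Drosophila melanogaster*. Heads were sieved from whole adults, whose stage the labels gave as mixed adult and whose sex they did not give. The study comprised 2 ChIP libraries and 2 input libraries, with 1 input serving each ChIP. The files held 3 lists of enriched regions: 1 for each ChIP replicate and 1 called by the authors for the replicate set, called the combined list here. No second tissue, genotype or treatment was compared, so the questions addressed were where the mark lay along the genome and how far the replicates shared its regions. Coordinates are those of FlyBase release 5. The lists carried no read totals, and the sequencing depth behind each region was therefore unknown. Nothing in the labels said that the replicates came from separate fly populations, so their spread can be technical.

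H3K4me1 regions covered close to 20% of the sequence in each replicate. Replicate 1 held 7785 regions over 29.3 Mb, which was 21.0% of the 139.7 Mb of sequence other than the unplaced extra scaffolds. Replicate 2 held 8341 regions over 25.3 Mb, or 18.1%. The replicates averaged 8063 ± 393 regions (SD, n = 2) and 27.3 ± 2.8 Mb (SD, n = 2). The combined list was larger than either, with 9680 regions over 38.7 Mb or 27.7%. Regions were kilobases wide, with a median of 2795 bp in replicate 1, 2207 bp in replicate 2 and 2694 bp in the combined list. No replicate region was narrower than 1301 bp, whereas the combined list went down to 1001 bp. Regions wider than 10 kb numbered 303 in replicate 1, 115 in replicate 2 and 651 in the combined list, where they held 24.3% of the covered bases. Within each list, wider regions had higher authors' scores, with a Spearman rho between width and score across regions of 0.75 in replicate 1, 0.69 in replicate 2 and 0.71 in the combined list.

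As called, the 5 broadest shared H3K4me1 regions of the combined list lay on chromosome arms 2R and 3R. This ranking depends on how regions were split: once regions within 500 bp were joined, 5 of the 10 widest domains were on the X. The 5 widest combined-list regions that overlapped a region of both replicates were 2R from 7476969 to 7528014 (51.0 kb), 3R from 11151043 to 11200058 (49.0 kb), 3R from 12040057 to 12086013 (46.0 kb), 2R from 13298367 to 13334005 (35.6 kb) and 3R from 16910333 to 16944788 (34.5 kb). Replicate 1 covered 90.2% to 97.7% of the bases of these regions and replicate 2 covered 84.3% to 92.8%. Each replicate broke them into smaller pieces: the 51.0-kb region on 2R was 6 regions in replicate 1 and 5 in replicate 2. Their authors' scores in the combined list lay between 0.95 and 1.04. No gene was assigned to these positions, because the gene table at hand was of another genome release.

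The strongest shared regions by the authors' score lay on 3R, 2R and the X. Among combined-list regions that overlapped a region of both replicates, the highest score was 1.73, at 3R from 27894097 to 27899701, a 5.61-kb region that ended 5.35 kb from the end of the arm. Next came 2R from 8919210 to 8931585, which was 12.4 kb wide and scored 1.66, and 3R from 9698713 to 9705055, which scored 1.60. Of the 10 highest, 4 were on the X: from 1867960 to 1872473 with a score of 1.54, from 8697794 to 8703894 with 1.53, from 2017450 to 2029855 with 1.51, and from 1855969 to 1865485 with 1.51. The others were 2R from 7360877 to 7366042, 3R from 675099 to 684151 and a 2.30-kb region of the unplaced sequence U from 5435699 to 5438000. The 2R region from 7360877 to 7366042 carried the highest score of the whole replicate 1 list, 1.61. In the unrestricted combined list, 19 regions scored above the 3R region from 27894097 to 27899701, none of them overlapping a region of both replicates.

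Most called regions lay on the euchromatic arms, and few lay in the mapped heterochromatin. Shares were taken over the full length of each sequence, without correction for bases where reads cannot be placed. Low coverage can therefore reflect missing reads as well as a missing mark. In the combined list, regions covered 36.6% of the X, 26.4% of 2L, 36.0% of 2R, 28.8% of 3L and 31.7% of 3R. Chromosome 4, the small dot chromosome with many repeats and heterochromatin proteins, had the highest share, at 47.3% in the combined list, 28.7% in replicate 1 and 37.9% in replicate 2. In replicate 1 the lead was small, as 2R was covered to 28.4%. The heterochromatic and unplaced sequences together were covered to 1.04% in the combined list, 0.388% in replicate 1 and 1.44% in replicate 2. The X heterochromatin was the exception among them, with 11.4% covered in the combined list, 8.80% in replicate 1 and 6.64% in replicate 2. This sequence is only 0.204 Mb long, and these shares rest on 8, 7 and 7 regions. Relative to the 4 large autosome arms, chromosome 4 was covered 1.54 times as densely in the combined list, 1.20 times in replicate 1 and 1.71 times in replicate 2. The ratio for chromosome 4 fell to 0.99 when only the higher-scoring 50% of the combined list was kept.

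**Figure D1:**
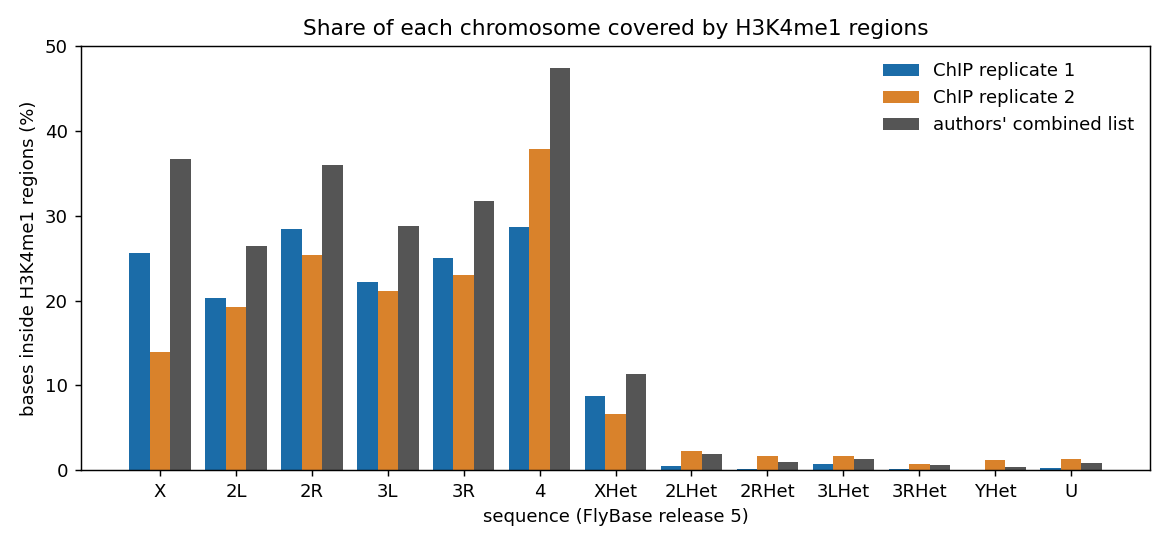
Share of the bases of each chromosome arm, of chromosome 4 and of the heterochromatic (Het) and unplaced (U) sequences inside H3K4me1 regions, in percent, for ChIP replicate 1, ChIP replicate 2 and the authors' combined list. Chromosome 4 reaches 47.3% in the combined list, and the X is covered to 25.6% in replicate 1 and 13.9% in replicate 2.

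Coverage dropped towards the centromeric end of the assembled sequence on 4 of the 5 large arms. In the combined list, the 2 Mb at this end were covered to 16.1% on the X, 14.5% on 2L, 11.1% on 2R and 6.73% on 3L. The rest of these arms was covered to 38.6%, 27.5%, 38.5% and 30.8%. On 3R the proximal 2 Mb were covered to 38.4%, against 31.2% of the rest. The separate sequence 3RHet was covered to 0.636%, and how much heterochromatin the end of each assembled arm includes was not examined. The direction on each of the 5 arms was shared by replicate 1 and replicate 2, with proximal-to-rest ratios on 3R of 1.21 and 1.27 and ratios on the other arms between 0.18 and 0.55. These proximal values were not tested, and the lack of a correction for unmappable bases limits them too.

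Among the large arms, the X differed most between the replicates. Regions covered 25.6% of the X in replicate 1 and 13.9% in replicate 2, a ratio of 0.54, while the ratio lay between 0.89 and 0.95 on 2L, 2R, 3L and 3R. In regions per Mb the gap was smaller: the ratio of replicate 2 over replicate 1 was 0.86 on the X and between 1.07 and 1.14 on these arms, where replicate 2 had more regions (6737 against 6100) that covered fewer bases. The X was covered 1.07 times as densely as the large autosome arms in replicate 1 (block bootstrap 95% interval 0.95 to 1.26) and 0.63 times in replicate 2 (0.56 to 0.74). The median X region was 2774 bp wide in replicate 1 and 2000 bp in replicate 2. On the autosome arms the medians were 2828 and 2338 bp. Coverage of the X was lower in replicate 2 in all 22 windows of 1 Mb, against 74 of the 97 autosome windows. The median log2 ratio of replicate 2 over replicate 1 was -0.84 in X windows and -0.11 in autosome windows, a difference of -0.73 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Chromosome 4 went the other way, with a ratio of replicate 2 over replicate 1 of 1.32, as did the heterochromatic and unplaced sequences, with 34 regions in replicate 1 and 123 in replicate 2. Windows along 1 chromosome are not independent, and the test describes these 2 libraries only.

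**Figure D2:**
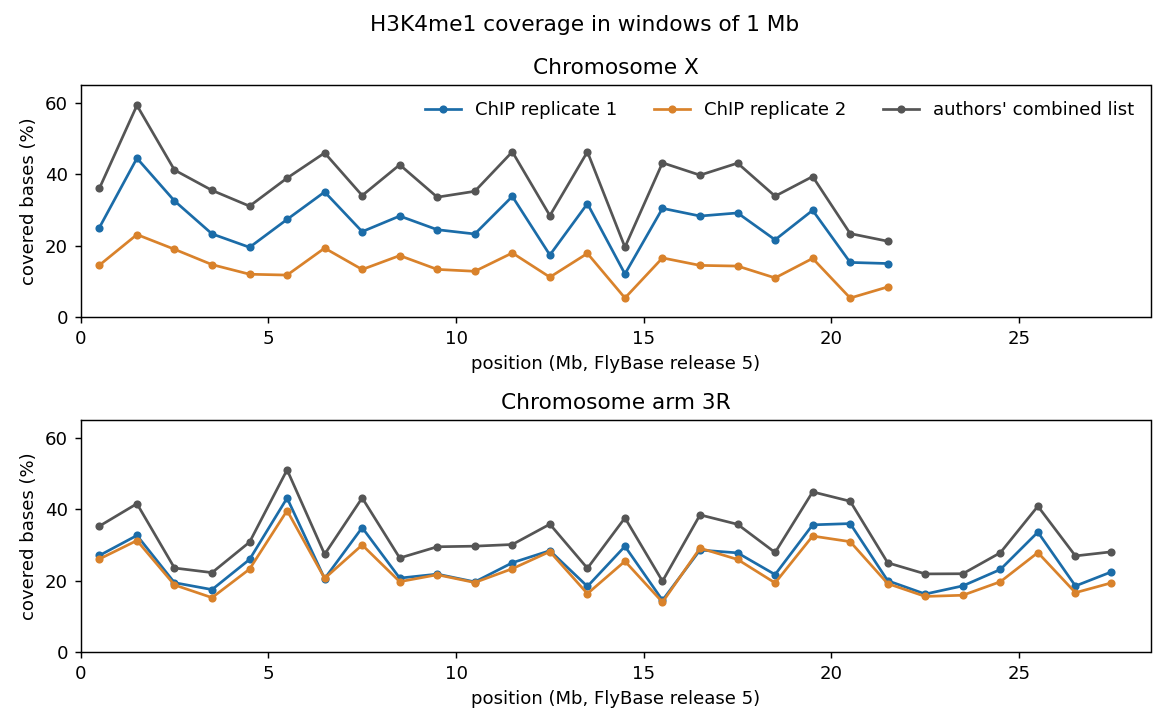
Share of bases inside H3K4me1 regions, in percent, in windows of 1 Mb along the X and along 3R, by position in Mb, for ChIP replicate 1, ChIP replicate 2 and the authors' combined list. Replicate 2 lies below replicate 1 in all 22 windows of the X, while the lines of the replicates run close together on 3R.

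Most regions were found in both replicates. Of the 7785 regions of replicate 1, 6018 or 77.3% (exact 95% binomial interval 76.4% to 78.2%) overlapped a region of replicate 2 by at least 1 bp, against 36.5% on average over circular shifts (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). In the other direction, 6716 of 8341 or 80.5% (79.7% to 81.4%) of the replicate 2 regions overlapped replicate 1, against 36.2% by chance (one-sided permutation p = 0.0001, again the smallest possible). The replicates shared 20.1 Mb, which was 58.2% of the bases covered in either. On the X, 59.2% (56.7% to 61.7%) of the replicate 1 regions were found in replicate 2, against 81.6% (80.6% to 82.5%) on the autosome arms. The replicate 2 regions of the X were found in replicate 1 to 84.4% (82.3% to 86.3%). Replicate 2 regions on chromosome 4 were found in replicate 1 to 65.3% (57.6% to 72.4%), and those of heterochromatic and unplaced sequence to 22.8% (15.7% to 31.2%). In the other direction the shares were 86.3% (79.2% to 91.6%) on chromosome 4 and 85.3% (29 of 34 regions) in heterochromatic and unplaced sequence. The intervals cover counting error only.

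Regions found in both replicates were wider and scored higher than regions found in 1 replicate. In replicate 1 the median width was 3375 bp for 6018 shared and 1820 bp for 1767 unshared regions, and the median score was 0.77 against 0.63. In replicate 2 the medians were 2567 against 1733 bp and 1.15 against 0.87 (two-sided permutation p = 1e-05 for each of the 4 differences, the smallest that 100000 resamples can give). Part of this is built in, because wide regions overlap more often by chance and score rises with width: circular shifts, which keep the widths, gave mean differences of 647 and 312 bp in width and 0.04 and 0.05 in score in replicates 1 and 2. The observed differences of 1555 and 834 bp and of 0.14 and 0.28 exceeded these (two-sided permutation p = 0.001 for each, the smallest that 1000 shifts can give). Among the replicate 1 regions in the highest score quartile, 99.5% (98.9% to 99.8%) of those on the autosome arms and 80.6% (77.1% to 83.7%) of those on the X were found in replicate 2. The 3 highest-scoring replicate 1 regions missing from replicate 2 were all on the X: from 5893593 to 5897340 with a score of 1.31, from 6770186 to 6774046 with 1.22, and from 13077070 to 13078660 with 1.19. The 3 highest-scoring replicate 2 regions missing from replicate 1 were 3LHet from 2137233 to 2139449 with a score of 3.87, 3L from 931179 to 932522 with 3.51, and U from 1081017 to 1082487 with the same 3.51. The first of these was in the combined list and the others were not. Of all replicate 2 scores, 49.1% were tied with another, and the number of reads behind these high scores was unknown. The ratios estimated from these 3 scores were 18 to 7, 2 to 1 and 2 to 1 in lowest terms, so the reads may be few. For the 3 replicate 1 regions on the X they were 53 to 17, 421 to 144 and 20 to 7, so the last may also rest on few reads.

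The order of region strength was shared in part. Across 3836 pairs of regions that overlapped one to one, the authors' scores in the replicates had a Spearman rho of 0.58 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give) and region widths a rho of 0.65. The rho of the scores was 0.32 over 569 pairs on the X and 0.62 over 3176 pairs on the autosome arms; this difference was not tested. These correlations are across regions, which are not independent replicates.

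The combined list held nearly all regions of replicate 1 and added regions of its own. Of the replicate 1 regions 99.7% (99.6% to 99.8%) overlapped the combined list, and of the replicate 2 regions 93.9% (93.4% to 94.4%). Among the 9680 combined-list regions, 5105 or 52.7% (51.7% to 53.7%) overlapped both replicates, 1458 overlapped replicate 1 only, 1087 overlapped replicate 2 only, and 2030 or 21.0% (20.2% to 21.8%) overlapped neither. The share found in neither replicate was 32.3% (30.2% to 34.4%) on the X and 18.1% (17.2% to 18.9%) on the autosome arms. Regions in neither replicate were narrow, with a median of 1324 bp against 4556 bp for those in both. The combined list was not independent of the replicates, so no chance test was made.

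H3K4me1 regions lay close together. The median gap from 1 combined-list region to the next was 2456 bp, against 5878 bp on average over random placements within each chromosome (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Gaps of at most 500 bp made up 21.2% of the gaps, against 5.82% by chance. Part of this can be built in. The placements also filled sequence where the lists held few regions, and calling can cut 1 broad domain into neighbouring pieces. The test therefore cannot tell clustering of the mark from these effects. Joining regions across such gaps left 7633 domains, of which 1001 were wider than 10 kb and held 41.9% of the bases. The widest domain, 2R from 8841292 to 8931585, joined 5 regions over 90.3 kb and contained the region with the second highest shared score. It was covered to 96.5% by replicate 1 and 92.2% by replicate 2. Of the 10 widest domains, 5 were on the X, led by a 63.9-kb domain from 15590217 to 15654118 that replicate 1 covered to 92.9% and replicate 2 to 65.6%.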

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

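All tests of this part were chosen after the result was seen, except that of the score on the X at matched replicate 1 score. That test too concerned a pattern found in these data, and the comparison of the X between the replicates was itself not planned. The change in coverage from replicate 1 to replicate 2 differed between chromosomes: the median log2 ratio in X windows minus that in autosome windows was -0.73 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Weaker enrichment of the X in replicate 2 stays open. Over 1021 one-to-one pairs in the top quartile of replicate 1, replicate 2 scores were compared at the same replicate 1 score. The X minus the autosome arms was -0.18 (two-sided permutation p = 0.0001, the smallest that 10000 resamples can give). Scores agreed less between the replicates on the X (rho 0.32 against 0.62), which can lower this value without weaker enrichment. The pairs are also not independent. Over all replicate 2 regions the median score was higher on the X (1.18 against 1.07 on the autosome arms). The same held in replicate 1 (0.81 against 0.71), so these medians do not speak to a change between the replicates. Over all one-to-one pairs the estimated X-to-autosome ratio of ChIP over input was 1.10 in replicate 1 and 1.03 in replicate 2 (difference -0.071, block bootstrap 95% interval -0.117 to -0.032). The same ratio was 1.08 in both over all called regions, which are not the same regions in each list. Fewer X-derived reads in replicate 2, as a pool with more males would give, also stays open: the X-to-autosome ratio of the input number per kb behind the scores was 0.67 in replicate 1 and 0.56 in replicate 2, a difference of -0.11 (block bootstrap 95% interval -0.13 to -0.10), and that of the ChIP number was 0.73 and 0.61. Lower depth or stricter calling in replicate 2 stays open too. The X ratio of covered share was 0.54 against 0.89 to 0.95 on the autosome arms. A loss of depth that is alike everywhere may still cost the X more calls, since the X already had the lower estimated numbers per kb in replicate 1 (ChIP 133 against 183, input 59.3 against 87.9). Heterochromatic and unplaced sequence had similarly low numbers there (ChIP 124, input 59.3), yet its covered share was 3.71 times as high in replicate 2. It held only 34 regions in replicate 1 and 123 in replicate 2. On the autosome arms the ChIP number per kb was estimated at 42.0 in replicate 2, below the 183 of replicate 1, while the input number was higher (115 against 87.9), and the labels give no biological difference between the replicates.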

How the results depend on the processing

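Alternatives on the X in replicate 2 relative to replicate 1, on spacing, on the score and width of shared regions, on the named regions and without the X were chosen after the data were seen; the others were planned. All 39 tested alternatives, on the shared regions, the rank correlation, the score and width of shared regions, the spacing and the X in replicate 2, kept their direction and stayed below 0.05 (highest permutation p = 0.001, the smallest that 1000 shifts can give). The share of replicate 1 regions found in replicate 2 ranged from 54.8% (50% reciprocal overlap) to 81.7% (without the X), and the reverse share from 51.2% to 82.7%. The X-to-autosome ratio of replicate 2 relative to replicate 1, 0.587 in the report's lists, ranged from 0.585 to 0.607 over 4 alternatives on the covered share and was 0.781 in regions per Mb, a weaker difference. Keeping the higher-scoring 50% of each replicate list lowered the mean number of regions to 4031 and the covered sequence to 18.6 Mb by construction. Keeping the higher-scoring 50% of the combined list alone, against the full replicate lists, raised the share of its regions found in a replicate. That share went from 79.0% to 93.3%, the cause of which was not tested. For the full combined list, the share found in either replicate alone was 64.0% to 67.8%, since fewer regions were compared. The X-to-autosome ratio of covered share was 1.20 in the combined list, above that of both replicates. It was 1.07 in replicate 1's own list and 0.629, the opposite direction, in replicate 2's own list. The combined list was not called anew without a replicate. The ratio for chromosome 4 fell from 1.54 to 0.994, close to no difference, in the higher-scoring 50% of the combined list, and the cause was not tested. All 15 named regions overlapped both replicates when 50% coverage was asked for, and when only the higher-scoring 50% of each replicate list was kept. Such agreement was largely built in, because the rule had picked regions that overlap both replicates and have the highest scores or widths. It says little about other regions. No paired analysis was possible because no file of the input libraries was used here; per the labels, each input had already served as the control of its own ChIP list. The planned promoter and gene-list alternatives were not run, because the gene table at hand is of another genome release. The unknown depth limits what a region missing from 1 replicate means.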

Other observations

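All tests of this part were chosen after the result was seen, except that of the distance to replicate regions. That test too concerned a pattern found in these data. H3K4me1 coverage varied widely along the arms. Among windows of 1 Mb, the combined list covered most in X from 1000001 to 2000000 (59.3%; replicate 1 44.5%, replicate 2 23.2%), followed by 2R from 3000001 to 4000000 (51.3%) and 3R from 5000001 to 6000000 (51.0%). The same X interval held 2 of the named regions with the highest shared scores. Least was covered at the centromeric ends of 3L, with 1.04% in the shorter last window from 24000001 to 24543557 and 1.81% from 23000001 to 24000000, and of 2R, with 4.59% in its first 1 Mb. Away from the 2 Mb at the centromeric ends of the arms, the longest stretches without a region in any of the 3 lists lay on 2L. They were 256 kb from 11541989 to 11798261, 215 kb from 4478039 to 4693475, 207 kb from 12218847 to 12425808 and 192 kb from 16910716 to 17102680. The lack of a correction for unmappable bases limits these low windows and stretches too. The part of the Y in heterochromatic sequence held no region in replicate 1, 2 regions in replicate 2 and 1 in the combined list.

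The 2030 combined-list regions found in neither replicate were weighed against the calling of the lists. In the combined list, 52.6% (exact 95% interval 50.4% to 54.8%) of them were at least as wide as the narrowest replicate region of 1301 bp. A replicate call at the same place could be narrower, so the shorter minimum width of the combined list stays open for these. For the 47.4% that were narrower it stays open too, because the width limit alone would keep them out of the replicate lists. The 2030 regions were not mainly fragments next to a replicate region, since 16.2% (14.6% to 17.9%) lay within 500 bp of one. This was still above the 6.47% seen over circular shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). Greater depth of the replicate set stays open and was not tested. On the autosome arms its estimated input number per kb was 194, against 87.9 and 115 in replicates 1 and 2. Its ChIP number was 189, against 183 and 42.0. These come from the regions of each list, which differ. No biological explanation was tested.

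The highest scores of the combined list sat in narrow regions: the 10 highest, from 2.48 to 3.78, had a median width of 1014 bp, and 7 of them, including the highest at 2L from 19356126 to 19357191, overlapped no region of either replicate. Scores were tied in 25.5% of the combined-list regions, as ratios of whole numbers would give. In lowest terms, the ratios behind these 10 scores had denominators of at most 7, against a median of 319 over the list, and the highest score was 9 to 1. The replicate 2 score of 3.51 at 3L from 931179 to 932522 and U from 1081017 to 1082487 was 2 to 1. The scores are consistent with ratios of few reads, which would make the top of this list a poor guide to the strength of the mark. With the scores read as natural or decimal logarithms, the median denominators were 6362468 and 6531216, so the whole-number form held on the log2 scale. No biological explanation was tested.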
